A study of Plutella xylostella with 12 samples.

How the data were processed

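RNA was measured in whole bodies of diamondback moth (Plutella xylostella) larvae in the middle of the fourth instar, with 8 larvae pooled in each sample. Per the labels' protocols, larvae grew at 25 °C on cabbage until early in the third instar and were then either moved to 10 °C or kept at 25 °C. The labels give the sex and the temperature of each sample, which makes 4 groups of 3 libraries. Replicate numbers come from the sample titles, and the female 25 °C libraries carry the numbers 1, 2 and 4.

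Per the labels' protocols, poly(A) RNA was made into libraries with a random-primed NEBNext Ultra II RNA kit and sequenced as paired reads on an Illumina NovaSeq. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Per the file headers, each deposited table gives whole-number read counts per gene as total, unique, exon and intron reads, and the authors' TPM and RPKM values beside them. Exon and intron counts added up to the total gene count in 100% of entries, and the deposited column called expression value equalled the RPKM column in 100% of entries. Total gene reads include reads that match several genes, so members of families with near-identical copies are uncertain. Strand use in counting is not given in the sources used here, so overlapping and antisense genes are uncertain too. The deposited TPM and RPKM values entered no test.

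The tables list 19364 features on 1428 scaffolds. Of these, 18895 carry locus identifiers, 13 are mitochondrial protein-coding genes with names and 456 are tRNA features. No product names stand in the tables. Locus identifiers were matched to a gene table of another assembly, ilPluXylo3.1, for symbols alone, and 10698 of them matched, of which 39 gave a symbol or a synonym other than the identifier. Positions printed here are those of the deposited tables. Neighbouring genes were taken from the same scaffold positions.

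Total gene reads ranged from 10183278 to 30106219 per library. A gene with 0 reads in a library is compatible with a level of up to 3 reads, which is 0.0996 CPM in the deepest library and 0.295 CPM in the shallowest. Such floors cover counting error only. Counts of each pair of libraries were compared with counting error, and no pair of libraries in a group matched within it.

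Main tests used edgeR 4.0.16 in R 4.3.3 on total gene counts with TMM scaling, the edgeR expression filter (a minimum count of 10 and a minimum total of 15) and robust quasi-likelihood fits. All 12 libraries entered a single fit with 4 group means, and 15027 genes were tested. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Levels are given as TMM-normalized CPM, mean ± SD over 3 libraries, and fold changes as log2 ± SE. This SE is an approximation: the absolute log2 change divided by the square root of the quasi-likelihood F statistic. The libraries are separate pools of larvae per the labels, and p-values measure the spread between these pools.

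The comparisons, the tests and most alternatives were fixed before the data were examined: cold in each sex, the difference between those responses, and the sex difference at each temperature. The comparison of 10 °C with 25 °C averaged over both sexes was added after seeing the data. So were the lists of mitochondrial mRNAs and of male-high genes, the exon-read and exon-length alternatives and the fits without doubted libraries. Alternatives fixed beforehand were DESeq2 size factors, no filter or a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma 3.58.1 voom with sample quality weights, fits of the compared groups alone, the replicate number as a block, uniquely mapped reads, a log2 change of at least 1, and leaving out each library.

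The rule for genes named in the text asked for the largest called changes with a product name, and for at most 2 identifiers in each direction where product names are missing. Every other identifier and every gene with a symbol was chosen after its values were seen. The 33 gene lists fixed beforehand were defined on product names, and 0 of them reached the 5 members that a set test needed, so none was tested. Set tests used camera with a preset correlation of 0.01, camera with an estimated correlation, and fry.

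Male-high genes were defined from the 6 libraries of 25 °C alone, fitted by themselves: adjusted p below 0.05, at least 16-fold higher in males and at least 5 CPM in males. These levels and lists were first computed without TMM scaling and then with it, so that they match the other levels given. Exon-length offsets removed each library's smooth trend of counts with the exon length of the gene. They were not centred within a library, so they also shifted libraries as a whole. The slope of gene level with exon length given below was fitted over the nuclear genes among those tested. Levels for it were each gene's log2 CPM minus that gene's mean over the 12 libraries. It therefore compares libraries with each other, and its sign gives no trend of absolute level with length within a library. Another slope, over 14480 genes with at least 1 CPM in 3 libraries, had other values, which are not given. In a self-test of the offsets on simulated data, an added trend of 0.222 log2 per doubling of length was reduced to 0.0263. The bound that this test had to meet was relaxed after a first bound failed.

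The main procedure was tested on counts simulated for the female cold comparison over 15027 genes, with 200 genes changed. With the spread of these libraries, 16 of 67 genes changed 4-fold were called, 50 of 67 at 16-fold and 58 of 66 at 64-fold, beside 6 unchanged genes. With a dispersion of 0.05, 61 of 67, 67 of 67 and 66 of 66 were called.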

Results

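The data are 12 RNA-seq libraries from whole fourth-instar larvae of the diamondback moth, a pest of cabbage crops, with 3 libraries for each combination of sex and temperature. Each library is a pool of 8 larvae. Female libraries held from 10183278 to 16885555 gene reads at 10 °C and from 10616570 to 15719846 at 25 °C. Male libraries held from 11883289 to 30106219 and from 12143738 to 17754105. The series asks whether the transcriptome response to cold depends on sex. Of 49 tested genes with a symbol, 13 are mitochondrial and 36 nuclear, and most other genes carry locus identifiers alone.

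Genes strongly higher in males at 25 °C did not follow the sex labels at 10 °C. There were 395 such male-high genes, defined from the 25 °C libraries alone after the data had been seen. Their median level, as a percent of the mean of the male 25 °C libraries, was 0, 8.86 and 33.6 in the libraries labelled female 10 °C replicates 1, 2 and 3, and 34.8, 55.5 and 0.097 in those labelled male 10 °C replicates 1, 2 and 3. At 25 °C it was 0, 2.15 and 0 in females and 98.2, 103 and 98.6 in males. The first principal component of log2 CPM held 55.7% of the variance and the second 20.7%. The second separated the sexes at 25 °C. At 10 °C it placed female replicates 2 and 3 on the male side and male replicate 3 on the female side. On the correlation of log2 CPM across genes, female 10 °C replicate 1 was closest to male 10 °C replicate 3 (r = 0.975), and female 10 °C replicate 3 was closest to male 10 °C replicate 1 (r = 0.96). Male 10 °C replicate 2 was closest to male 25 °C replicate 3 (r = 0.96), and female 25 °C replicates 1 and 2 were both closest to female 10 °C replicate 1 (r = 0.945 and 0.948). Female 10 °C replicate 2 was closest to male 10 °C replicate 3 (r = 0.919). Genes are not independent replicates, and these values describe the libraries without a test.

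**Figure D1:**
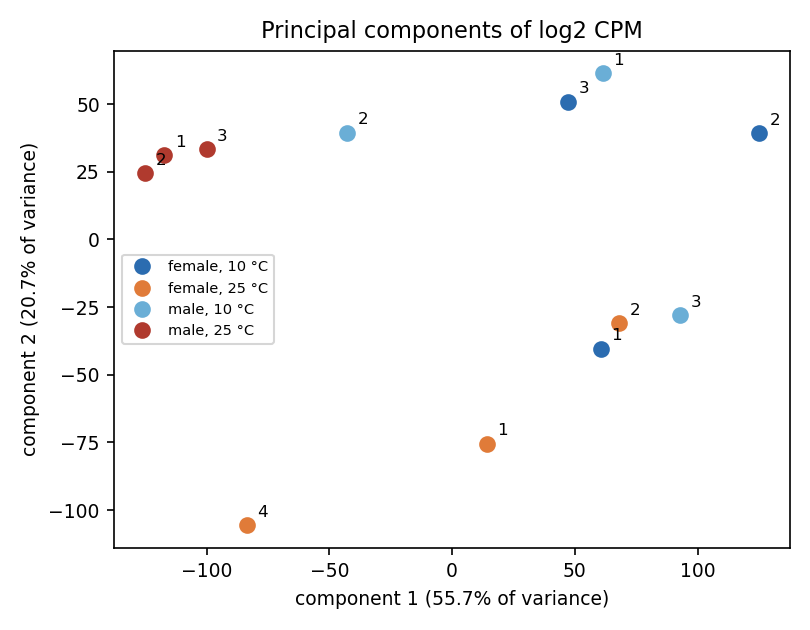
Each point is a library, placed by its scores on the first and second principal components of log2 CPM, which hold 55.7% and 20.7% of the variance; colours give sex and temperature, and numbers the replicate. The 3 male 25 °C libraries lie together. The 10 °C libraries of both sexes lie among each other on the first component, except male replicate 2, at -42.8. Female 25 °C replicate 2, at 68.0 on it, lies among the 10 °C libraries. On the second component, 25 °C females lie at -75.4, -30.9 and -105.6 and 25 °C males at 31.15, 24.58 and 33.33. At 10 °C, female replicate 1 (-40.3) and male replicate 3 (-27.9) lie on the side of the 25 °C females. Female replicates 2 and 3 (39.4 and 50.9) lie with male replicates 1 and 2 (61.35 and 39.4).

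**Figure D2:**
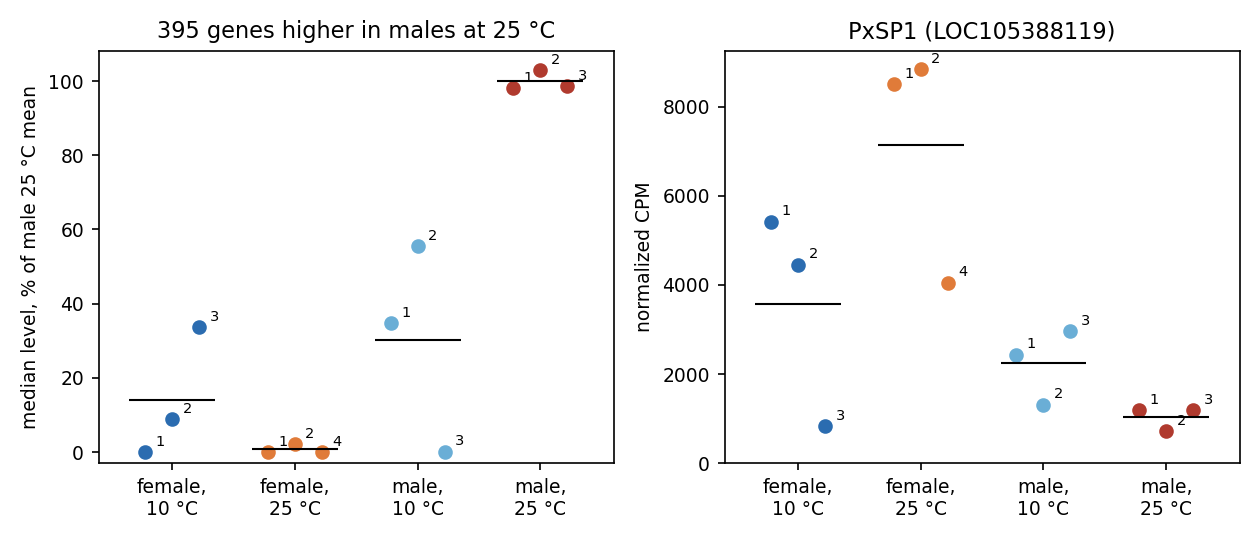
Levels of sex-dependent genes in each library by group, each point being a library with its replicate number. Male-high genes are at 33.6% of the male 25 °C mean in female 10 °C replicate 3 and at 0.097% in male 10 °C replicate 3.

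In females, 6 of 15027 genes fell at 10 °C and 0 rose (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), and 2587 genes had an unadjusted p below 0.05. Among these 6 genes the largest change was that of LOC105381203 (scaffold NW_011952052, 1220204 to 1226260), from 43.1 ± 19.49 CPM to 1.26 ± 0.245 CPM (log2 fold change -5.08 ± 0.44, n = 3, edgeR adjusted p = 0.00124). LOC105383572 fell from 8.92 ± 3.56 to 0.272 ± 0.0909 CPM (-4.98 ± 0.69, edgeR adjusted p = 0.0329). LOC105386543 and LOC105387993, chosen because males share the call, fell too (log2 -3.29 ± 0.37 and -3.76 ± 0.46). Of the 2536 reads of LOC105386543 over all libraries, 8 mapped uniquely, so it was not tested on unique reads, and its reads cannot be assigned to this locus with certainty. None of the 6 has a symbol. In counts simulated for this comparison with the spread of these libraries, 50 of 67 genes changed 16-fold and 16 of 67 changed 4-fold were called. Among heat shock genes, hsp19.5, a small heat shock protein gene, had a log2 change of -2.04 ± 0.75, the constitutive chaperone hsc70 -0.83 ± 0.38, Hsp90 -0.10 ± 0.35 and Hsp69, a relative of hsc70, 1.47 ± 0.71, with edgeR adjusted p from 0.251 to 0.882. The midgut-type serine protease Tryp_SPc1 was at 1682 ± 850 CPM at 10 °C and 6083 ± 2709 CPM at 25 °C (-1.85 ± 0.68, edgeR adjusted p = 0.249), and the phosphoglucomutase gene Pgm, of sugar metabolism, had -0.89 ± 0.47. Of the 13 mitochondrial mRNAs, 12 had a negative log2 change (median -0.92), and 0 passed the test over all genes or adjusted over the list alone. Camera gave p = 0.00172 for this list and p = 0.33 with an estimated correlation, and fry gave p = 0.232. The male-high genes had a median log2 change of 3.83 in this comparison (estimated-correlation p = 0.3), with female 10 °C replicates 2 and 3 above the 25 °C females. The count was 1 without female 10 °C replicate 2, 1 without female 10 °C replicate 3, 19 without female 25 °C replicate 1 and 23 without female 25 °C replicate 2. It was 0 without female 10 °C replicate 3 and male 10 °C replicate 3, 742 with DESeq2 (217 higher, 525 lower), 1635 with voom (685 higher, 950 lower) and 0 when the female libraries were fitted alone. LOC105383572 lost its call when female 10 °C replicate 1, 2 or 3 or female 25 °C replicate 4 was left out (-5.24, -4.76, -4.99 and -4.63). LOC105386543 and LOC105387993 lost theirs without female 10 °C replicate 1 (-3.18 and -3.47), 2 (-3.31 and -4.09) or 3 (-3.40 and -3.80).

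In males, 3 genes fell at 10 °C and 0 rose, and 4813 genes had an unadjusted p below 0.05 in the same edgeR test. LOC105381203 fell from 80.2 ± 20.2 to 1.51 ± 0.273 CPM (log2 fold change -5.72 ± 0.45, n = 3, edgeR adjusted p = 0.000442). LOC105387993 (NW_011952205, 283580 to 287689) fell from 55.7 ± 14.8 to 2.71 ± 0.782 CPM, and LOC105386543 (NW_011952163, 105193 to 107344) from 43.1 ± 10.3 to 4.36 ± 0.527 CPM, with log2 changes of -4.36 ± 0.47 and -3.30 ± 0.37 (edgeR adjusted p = 0.0058 for both). No gene with a symbol passed. The Hox gene Ubx was at 10.3 ± 2.82 CPM at 10 °C and 2.92 ± 0.85 CPM at 25 °C (1.81 ± 0.52, edgeR adjusted p = 0.0638). The gene with the symbol actin was at 6503 ± 3949 and 1774 ± 295 CPM (1.87 ± 0.64, edgeR adjusted p = 0.0845), with 54.5% of its reads mapped uniquely. For hsp19.5 the log2 change was -1.96 ± 0.75, for Hsp90 0.00 ± 0.35, for Hsp69 -0.10 ± 0.69 and for Pgm -0.98 ± 0.47. All 13 mitochondrial mRNAs had negative log2 changes (median -1.33), of which 0 passed over all genes or adjusted over the list alone. Camera gave p = 1.77e-05 for the list, p = 0.19 with an estimated correlation, and fry gave p = 0.0485. The male-high genes had a median log2 change of -1.73 (estimated-correlation p = 0.267), and their summed level in male 10 °C replicate 3 was 199 CPM, against 5468 and 8144 CPM in male 10 °C replicates 1 and 2. The count was 3219 without male 10 °C replicate 2 (2228 higher, 991 lower), and 1 without male 10 °C replicate 1 or 3, when LOC105386543 (-3.28 and -3.22) and LOC105387993 (-4.27 and -4.22) lost their calls. It was 1 without female 10 °C replicate 3 and male 10 °C replicate 3, 3547 with DESeq2 (2713 higher, 834 lower), 7052 with voom (4096 higher, 2956 lower) and 1085 when the male libraries were fitted alone (855 higher, 230 lower). Most calls of the last 3 fits were higher at 10 °C.

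**Figure D3:**
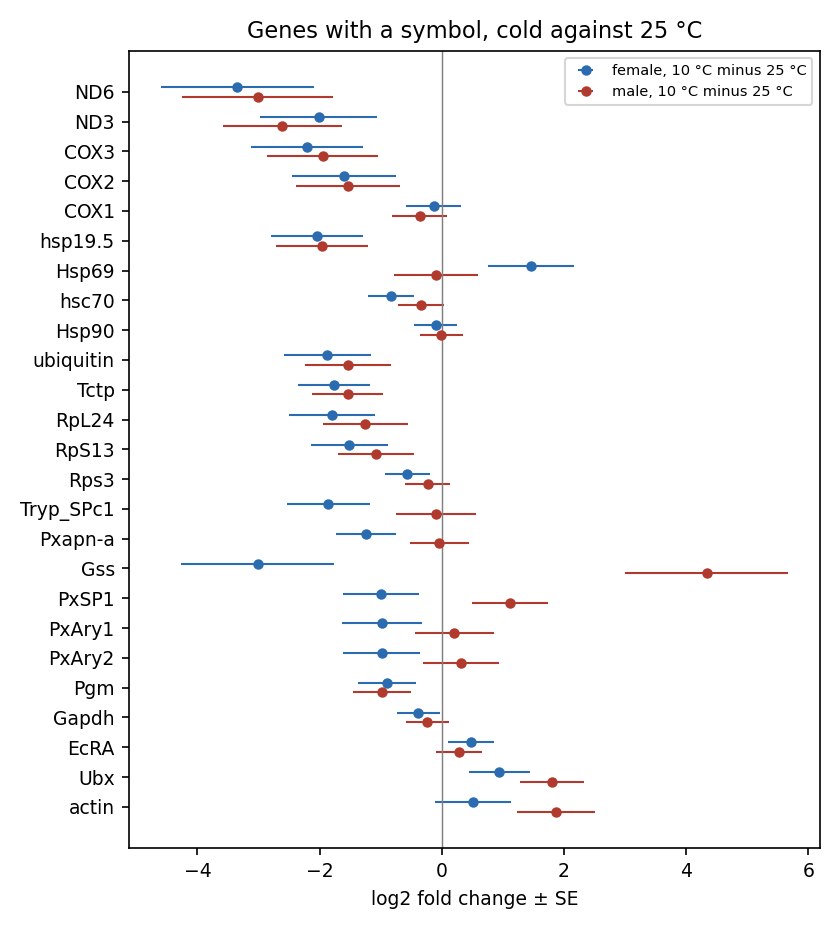
Log2 fold change of 10 °C against 25 °C (x axis) with its SE for genes with a symbol, in females (blue) and males (red), from edgeR over 3 libraries per group. None of the genes plotted passed an adjusted p of 0.05 in either sex; ND6 was at -3.34 in females and -3.01 in males.

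Averaged over both sexes, 2054 genes rose and 1399 fell at 10 °C, 3453 in all, with 6612 at an unadjusted p below 0.05. This comparison was added after the data had been seen. The median log2 change of all tested genes was 0.233. TMM factors ran from 0.94 to 1.65 at 10 °C and from 0.59 to 1.17 at 25 °C, so the sign of small changes rests on the scaling. Of the 49 genes with a symbol, 8 fell and 2 rose, close to the share of 3453 in all 15027 genes. The mitochondrial genes ND6 and ND3, which encode NADH dehydrogenase subunits, fell (log2 -3.18 ± 0.88 and -2.31 ± 0.68), as did COX3, a cytochrome c oxidase subunit gene (-2.08 ± 0.64; edgeR adjusted p = 0.0337, 0.038 and 0.0424). COX1, of the same complex, had -0.24 ± 0.32 (edgeR adjusted p = 0.565). Further genes that fell were hsp19.5 (-1.998 ± 0.53), ubiquitin (-1.70 ± 0.50), the growth-related gene Tctp (-1.65 ± 0.41), the ribosomal protein gene RpL24 (-1.52 ± 0.49) and PxSDF2-l1 (-0.81 ± 0.25), which has 55.9% of its reads mapped uniquely and lost its call on unique reads. Ubx (1.38 ± 0.36) and the acetylcholinesterase gene ace1 (2.96 ± 0.99) rose (edgeR adjusted p = 0.031 and 0.0498). At 25 °C ace1 was near 0 reads, at 0.64 ± 1.0 CPM in females and 0.11 ± 0.18 CPM in males. Its highest group mean, at 10 °C in males, was 2.34 CPM. Hsp90 (-0.05 ± 0.25), Gapdh (-0.31 ± 0.25) and actin (1.19 ± 0.44) did not pass. For the 13 mitochondrial mRNAs the median was -1.25. Of them, 3 passed over all genes, close to the share of 3453 in all 15027 genes, and 5 adjusted over the list alone. Camera gave this list p = 3.51e-05, an estimated correlation p = 0.202 and fry p = 0.0316. DESeq2 called 5932 genes and voom 7633. The count, and with it the balance of higher and lower calls, changed with most single libraries. It was 173 (58 higher, 115 lower) without female 10 °C replicate 2, 159 (70 and 89) without female 10 °C replicate 3, 264 (97 and 167) without male 10 °C replicate 1, 155 (53 and 102) without male 10 °C replicate 3 and 5275 (2965 and 2310) without male 10 °C replicate 2. At 25 °C it was 190 (51 and 139), 5803 (3429 and 2374) and 1739 (1249 and 490) without female replicate 1, 2 or 4. It was 96 (23 and 73), 55 (13 and 42) and 1183 (756 and 427) without male replicate 1, 2 or 3. Of the 10 calls among genes with a symbol, 8 were left without female 10 °C replicate 1, 10 without male 10 °C replicate 2 or female 25 °C replicate 2, 1 (Ubx) without female 25 °C replicate 4 or male 25 °C replicate 3, and 0 without any other single library. Without female 10 °C replicate 3 and male 10 °C replicate 3 the count was 8 (1 higher, 7 lower), and 0 of the 10 calls were left. A block for the replicate number gave 20 (1 higher, 19 lower), again with 0 of the 10 calls left. Female 25 °C replicate 4, alone with its number, adds nothing to the comparison in that fit.

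Relative to each gene's mean over the 12 libraries, short transcripts stood lower than long ones in most 10 °C libraries. In the averaged comparison the median log2 change was -0.21 for the shortest of 4 equal classes of genes, with exons of at most 1044 bp in total, and 0.55 for the longest, with at least 2567 bp. ND6, ND3, hsp19.5, ubiquitin, Tctp and RpL24 all have exon lengths below that lower limit, from 354 bp for ND3 to 883 bp for Tctp. PxSDF2-l1, which also fell, has 1890 bp and Hsp90 has 2514 bp. Of the genes with a symbol that rose, Ubx has 2593 bp, above the limit of the longest class, and ace1 has 1568 bp. The slope with exon length was taken on these relative levels, so its means at 10 °C and 25 °C mirror each other. It was 0.141 ± 0.188 log2 CPM per doubling over the 6 libraries at 10 °C and -0.141 ± 0.171 over the 6 at 25 °C (exact permutation test, two-sided, p = 0.026). Within females it was 0.211 ± 0.177 and -0.0212 ± 0.172 (exact p = 0.3), and within males 0.071 ± 0.206 and -0.261 ± 0.0282 (exact p = 0.1, the smallest that 3 against 3 allow). With offsets that remove this trend from each library, 1689 genes rose and 2086 fell in the averaged comparison, so that lower calls outnumbered higher ones. The offsets also shifted whole libraries, and log2 changes moved by a median of -0.147 over all genes. The turn in the balance can therefore not be credited to length alone. With these offsets 9 of the 10 calls among genes with a symbol were left, ace1 being the exception. A length trend was not particular to cold. For females against males at 25 °C the median log2 difference was -0.16 in the shortest class and 0.41 in the longest.

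**Figure D4:**
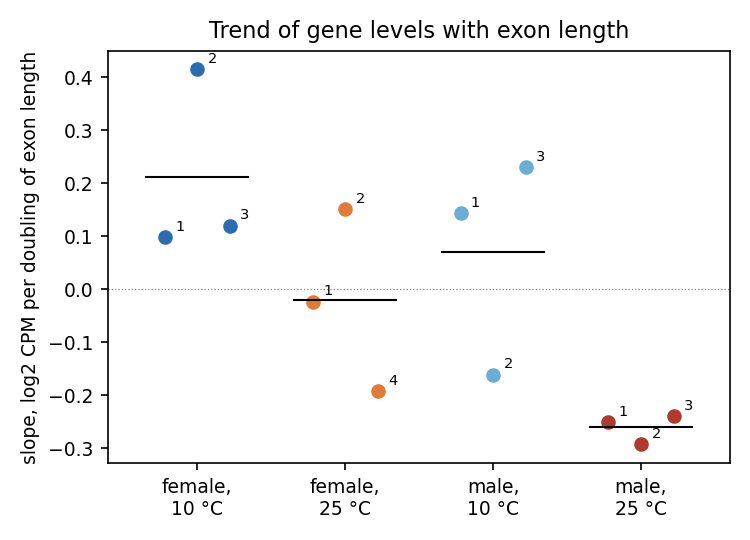
Slope of relative gene level with total exon length, in log2 CPM per doubling (y axis), for each library by group. Levels are relative to each gene's mean over the 12 libraries. The replicate number stands beside each point, with a line at each group mean. The slope is -0.239 or lower in the 3 male 25 °C libraries and highest, 0.415, in female 10 °C replicate 2.

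The cold responses of females and males, which share no library, were alike in sign for 77.9% of the 15027 genes (Pearson r = 0.412 and Spearman rho = 0.588 across genes, which are not independent replicates). LOC105381203, LOC105386543 and LOC105387993, the 3 genes called in males, were all among the 6 called in females, beside 0.0012 shared genes expected of independent lists. The lists are not independent, because a single fit gave both and used a shared spread for each gene. The expected value may therefore be too low. Without female 10 °C replicate 3 and male 10 °C replicate 3, 0 genes were called in females, 1 in males and 0 in both, while the log2 changes of LOC105381203, LOC105386543 and LOC105387993 stayed near their size (-4.99, -3.40 and -3.79 in females, -5.60, -3.22 and -4.22 in males). In that fit r was 0.517, rho 0.622 and the share alike in sign 76.7%. LOC105381203 was at most at 1.80 CPM in each library of 10 °C and at least at 24.1 CPM in each of 25 °C.

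The difference between the cold responses of females and males, the question of the series, was past the threshold for 0 of 15027 genes in edgeR, with 1351 at an unadjusted p below 0.05, while DESeq2 called 15 and voom 370. Gss, a glucosinolate sulfatase gene whose product disarms defence compounds of cabbage plants, had the largest difference among genes with a symbol. Its log2 change with cold was -3.01 ± 1.25 in females and 4.34 ± 1.33 in males (difference -7.35 ± 1.83, edgeR adjusted p = 0.548). Its levels were 31.2 ± 13.5 and 251 ± 211 CPM in females at 10 °C and 25 °C, and 244 ± 349 and 12.1 ± 5.18 CPM in males, over a gene model with 345 bp of exon. Hsp69 had a difference of 1.56 ± 0.98, Tryp_SPc1 of -1.77 ± 0.93 and PxSP1 of -2.11 ± 0.88. The arylphorin storage protein genes PxAry1 and PxAry2 had -1.18 ± 0.92 and -1.29 ± 0.88, and actin -1.36 ± 0.88. None of these passed. The mitochondrial mRNAs had a median difference of 0.40 (camera p = 0.0171, estimated-correlation p = 0.456, fry p = 0.544). Leaving out any single library left the count at 0. Female 10 °C replicate 3 and male 10 °C replicate 3 went against their sex labels in the male-high genes. Leaving out both also gave 0 in edgeR, with 628 genes at an unadjusted p below 0.05. The values per gene above rest on the groups as labelled. With these labels in doubt, the count of 0 does not show that the responses are alike.

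At 25 °C, 0 of 15027 genes differed between the sexes in the edgeR fit of all libraries, with 3369 at an unadjusted p below 0.05, while DESeq2 called 2041 genes (1209 higher and 832 lower in females) and voom 4658 (2606 and 2052). Which sex had more of the higher genes depended on the fit. Long transcripts stood higher and short ones lower in females here, as given above, and these counts do not remove that trend. Fitted on the 25 °C libraries alone, edgeR called 592 genes, 43 higher in females and 549 higher in males. The following genes are from that fit, chosen after their values were seen. LOC105388767 was at 1.29 ± 1.91 CPM in females and 367 ± 30.9 CPM in males (log2 female against male -7.85 ± 1.22, n = 3, edgeR adjusted p = 0.0103), and LOC105380254 at 52.3 ± 18.8 and 1197 ± 316 CPM (-4.48 ± 0.37, adjusted p = 0.00126). LOC105381553 was higher in females, at 17860 ± 3272 against 2574 ± 345 CPM (2.85 ± 0.35, adjusted p = 0.00391), with 13.4% of its reads mapped uniquely, as was LOC105388120, at 20630 ± 5125 against 4139 ± 1176 CPM (2.40 ± 0.43, adjusted p = 0.0175). In the fit of all libraries, PxSP1 was at 7135 ± 2677 CPM in females and 1034 ± 278 CPM in males (2.79 ± 0.66, edgeR adjusted p = 0.0842). PxANTI2 had -3.91 ± 1.10 (adjusted p = 0.0882), Gss 4.38 ± 1.34 (0.0986), Hsp69 -1.79 ± 0.71 (0.168) and actin 1.69 ± 0.63 (0.146). PxAry1 and PxAry2 had 0.08 ± 0.65 and 0.24 ± 0.62, and PxAry1 stood at 13360 ± 3655 CPM in females and 12670 ± 497 CPM in males. In the fit of all libraries the count was 1745 without female 25 °C replicate 4, of which 1500 were higher in females, and 6 without female 25 °C replicate 1, all higher in females. It was 550 (73 higher and 477 lower in females) without female 10 °C replicate 3 and male 10 °C replicate 3. These are in neither group compared here, but leaving them out changed the shared spread, the scaling and the genes tested (15353). With all libraries kept, DESeq2 size factors, no filter and the 1 CPM filter each left the count at 0. This argues against the scaling or the genes tested by themselves as the reason, in those settings. The shared spread was not varied alone.

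At 10 °C, 0 of 15027 genes differed between the libraries labelled female and male in edgeR, with 120 at an unadjusted p below 0.05, and DESeq2 and voom also called 0. PxSP1 was at 3568 ± 2417 CPM in females and 2238 ± 844 CPM in males (log2 0.67 ± 0.62), with 832 CPM in female 10 °C replicate 3 and 2965 CPM in male 10 °C replicate 3. LOC105381553 had 0.26 ± 0.56, LOC105388120 0.47 ± 0.56, LOC105380254 -1.33 ± 0.72 and LOC105388767 -1.0 ± 1.61, all with an edgeR adjusted p of 1.00. Gss had -2.97 ± 1.25, and PxAry1 and PxAry2 -1.11 ± 0.65 and -1.05 ± 0.63. The 395 male-high genes had a median log2 difference of -1.08 here and -6.38 at 25 °C (camera estimated-correlation p = 0.377 and 0.0309), and 0 of them were lower in every female than in every male library at 10 °C. That list was chosen on the 25 °C libraries, so its 25 °C value is not independent evidence. The count stayed 0 without any single library of 10 °C. It also stayed 0 without both female 10 °C replicate 3 and male 10 °C replicate 3, when 898 genes had an unadjusted p below 0.05. Libraries of 25 °C, which enter the same fit, were not left out singly for this comparison.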

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

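Apart from the gene by gene test of the difference between the cold responses, the tests in this part were chosen after the results were seen.

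The 395 male-high genes had a median log2 difference of 5.33 between the cold responses of the sexes, but they were chosen for a sex difference in the same 25 °C libraries, which largely fixes the sign and size of that value, and no test independent of that choice was run. An exchange of the libraries labelled female 10 °C replicate 3 and male 10 °C replicate 3 needs the female-high genes out of place too. Of these, 25 of 28 (89.29%) were higher in the library labelled male. But their median was also raised in male 10 °C replicate 1, at 85.4% of the female 25 °C mean. It was 67.2% in female 10 °C replicate 3 and 10.2 to 15.1% in males at 25 °C. Among the female 25 °C libraries themselves it ran from 45.7 to 143%. The female-high genes are also long, with a median exon length of 3331.5 bp against 1119 bp for the male-high genes. The length slope was 0.230 in male 10 °C replicate 3 and 0.144 in male 10 °C replicate 1. In female 10 °C replicate 3 it was 0.120. Levels of the female-high genes may thus follow length as well as sex, and these were not separated. Of 5 genes on in females and off in males by a rule on the 25 °C libraries alone, the median was 79.3, 114 and 7.34% of the female 25 °C mean in female 10 °C replicates 1, 2 and 3 and 4.58, 8.82 and 91.1% in the male ones, but only LOC105398194 and LOC105390973 (40%), both seen before the rule was set, were lowest in replicate 3 of the females and also highest in replicate 3 of the males, so 5 genes do not decide whether a cold effect was alike in all pools of a label. Whether cold lowers the male-high genes stays open: their level of 33.62% of the male 25 °C mean in the library labelled female 10 °C replicate 3 would count against it only if that label holds, and the rule for this test was changed after its value was seen, the first rule having counted against it. An exchange, pools of mixed sex, male RNA mixed into female 10 °C replicate 2, where 90.13% of the male-high genes (356 of 395) lay above their highest female 25 °C level, just past the bound of 90 set for it, and an untested change of sex-dependent expression that differs between cold pools all stay open, and no library was regrouped.

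Intron reads made up 6.394% of gene reads in the female 10 °C libraries and 4.23% in the female 25 °C libraries (exact permutation p = 0.1, the smallest possible with 3 against 3), in counts that the comparisons do not use by themselves. In males the values were 4.96% and 4.37% (exact p = 0.4), and over both sexes 5.68% and 4.30% (n = 6, exact permutation p = 0.0281).

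Short transcripts were lower and long ones higher at 10 °C. If RNA integrity or fragment size differed between libraries, the length slope of the 13 mitochondrial mRNAs, read within each temperature, was to follow that of nuclear genes. The lower of the correlations within a temperature was -0.238 (n = 6, exact permutation p = 0.708), with a 95% interval from -0.88 to 0.711, so the positive relation was not found and 6 libraries cannot exclude it. The rule first written, a correlation under 0.2, would have counted against this explanation; a requirement on the interval was added after the value was seen, so integrity and temperature cannot be told apart here. As the whole cause of the averaged calls the trend is argued against, since 83.06% of the 3453 calls (2868) passed in the same direction with length offsets.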

How the results depend on the processing

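The averaged comparison, the exon-read and exon-length settings and the fits without named libraries were chosen after seeing the data, as were all tests by other splits of the libraries. The balance of higher and lower calls did turn: from 0 higher and 3 lower to 2713 and 834 with DESeq2 in males, and from 2054 and 1399 to 1689 and 2086 with exon-length offsets in the averaged comparison. For named genes, no called value changed sign; 2265 values under alternatives stayed on their side of the threshold, some uncalled ones changing sign within their SE, 200 lost the call, 117 gained it and 40 uncalled ones changed sign by more than their SE. Their cause was not tested.

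Counts below are in the order cold in females (6 in the main test), cold in males (3), sex at 25 °C (0) and cold averaged (3453). DESeq2 gave 742, 3547, 2041 and 5932 and voom 1635, 7052, 4658 and 7633, and for the difference between the responses 15 and 370. Fits of the compared groups alone gave 0, 1085 and 592 for the first 3. Without a filter, females had 10. Exon-length offsets gave 18, 5, 1 and 3775, and moved log2 changes by a median of -0.11 in females, -0.17 in males and -0.147 averaged. Without female 10 °C replicate 3 and male 10 °C replicate 3 the counts were 0, 1, 550 and 8. Without female 10 °C replicate 2 as well they were 0, 1, 605 and 2, with 2 for sex at 10 °C, and with length offsets added 0, 0, 734 and 0, with 28. Leaving out single libraries gave 1 to 23, 1 to 3219, 0 to 1745 and 55 to 5803, and 0 for sex at 10 °C and for the difference between the responses. For each comparison, only libraries of the groups compared were left out singly. DESeq2 size factors, the 1 CPM filter, unique reads, exon reads and the log2 minimum of 1 moved no count by over 1.5 times; on unique reads 5 of the 6 female and 2 of the 3 male calls could be tested, LOC105386543 not being among them.

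With the replicate number as a block the counts were 1, 541 (482 higher, 59 lower), 0 and 20 (1 higher, 19 lower, with 0 of the 10 calls among genes with a symbol), and 0 for sex at 10 °C and for the difference between the responses. The numbers share no stated origin, and correlations of same-numbered deviations ran from 0.082 to 0.603 in the female and from -0.082 to 0.112 in the male cold comparison, with -0.488, -0.465 and -0.716 between the sexes at 10 °C. The numbers were therefore not taken as pairs, and not every library correlated best with its own number.

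Of the 10 splits of the 6 libraries, the real one gave 6 genes for cold in females and 3 in males, and the highest other split gave 0 in each. Those splits are too few for a share under 0.05. Where the real count is 0, as for sex at 25 °C (10 of 10), sex at 10 °C (10 of 10) and the difference between the responses (100 of 100 drawn), every split reaches it by construction, so nothing follows about chance. The highest other split gave 0, 36 and 0, and the 36 came from the split at 10 °C that places the library labelled male 10 °C replicate 3 with female replicates 1 and 2, which points to a structure of the samples. For cold averaged, 1 of 100 splits, the real one, gave 3453 and the highest other 1997. This argues against chance among these drawn splits only, for a comparison and a test both chosen after the data were seen. The 1997 points to structure among the libraries. The counts above of 55 without male 25 °C replicate 2, 8 without female and male 10 °C replicates 3, and 20 with the block limit it further. They show how far 3453 rests on few libraries and on the fit.

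The 33 lists fixed beforehand had 0 with 5 members and were not run, nor were their alternatives. In the female comparison, at these depths, 16 of 67 simulated 4-fold changes were called with the spread found and 61 of 67 at a dispersion of 0.05; depth was not varied.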

Other observations

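All tests in this part were chosen after the results were seen.

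Single-exon genes were more frequent among the 395 male-high genes than among tested genes of matched length. Of the 395, 17.72% (70) had a single exon, beside a mean of 8.85% and a highest value of 14.2% in 10000 sets of tested genes matched on exon length (permutation p = 1e-04, the smallest these sets can give), so short transcripts are argued against as the whole reason. They also stood beside each other in the assembly, with 37 adjacent pairs against at most 19 in 1000 random sets of tested genes, which argues against random placement. LOC105386961 (NW_011952010, 2496091 to 2498044) had a mean of 22.4 CPM in male 25 °C libraries and 0.0181 CPM in female ones. LOC105382430 (NW_011952010, 1402426 to 1403455), with 1 exon, was at 27.3 and 0.0905 CPM. These genes lie far apart on their scaffold and are not given as an adjacent pair. All 1083 reads of LOC105386961 and all 1568 of LOC105382430 mapped uniquely. Whether the male-high genes as a set are copies of each other that share reads was not tested.

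A set of 25 genes stood above 20 CPM in female 25 °C replicates 2 and 4 and below 5 CPM in every 10 °C library. Their summed level was 3291 and 2781 CPM in those libraries, 195 CPM in female 25 °C replicate 1, 144, 549 and 159 CPM in male 25 °C replicates 1, 2 and 3, and 15.1 to 20.7 CPM at 10 °C. LOC105381203 and LOC105387993, called in both sexes, are members. LOC105391598, LOC105391599 and LOC105391591 lie in a run on scaffold NW_011952350 and summed to 1307 CPM in female 25 °C replicate 2, but to 180 CPM in female 25 °C replicate 4, 152 CPM in male 25 °C replicate 2 and 19.8 CPM in female 25 °C replicate 1. The 25 genes held 4 adjacent pairs, against at most 2 in 10000 random sets, so neighbours switched together may be part of the pattern. Without TMM scaling the same limits gave 18 genes, 17 of them shared, and 1 pair against at most 1 in random sets, so the explanation depends on the scaling and stays undecided.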
